A study of Mus musculus with 2 samples.

How the data were processed

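RNA from KPC2 wild type cells and from KPC2 cells maintained in 260 ng/mL gemcitabine was sequenced, 1 library per group, per the labels. The submitters' processing notes list HISAT2, StringTie and the mouse genome build GRCm38, with no role or version, so which tool made which value is not given in the sources used here. The deposited table has 1 row per Ensembl gene, 55468 rows, with a value for each library. Its header names no unit. The values were read as FPKM made by the authors, because they are not whole, their sums differ between the libraries (998508 and 1197280), and low values of single-transcript genes fall on whole multiples of 1 step once multiplied by length. The authors also deposited a log2 fold change without a pseudocount, a test statistic (a score with no fixed range) and a p-value and q-value per gene, per the file headers. Their test rests on 1 library per side, and its calls are quoted only as the authors'. The highest q-value among the 56 genes that the authors called was 0.0495.

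Genes were placed with the GENCODE M21 annotation, which is on GRCm38. Of the gene identifiers, 55227 were found there, all on the authors' chromosome, and 99.9% of these genes lay inside the authors' locus. Because 25101 rows share a locus with another row, overlapping genes can share fragments, and the table does not say how those were split. For genes with 1 transcript of 1000 to 8000 bases, FPKM times length less 160 bases came within 0.1 of a whole number of fragments for 92.8% of low values in the wild type library and 93.8% in the resistant one, up to 5.5 fragments. For 1 kb of length left after the 160 bases are taken off, 1 fragment was worth 0.0417 FPKM in the wild type and 0.0431 FPKM in the resistant library. Intervals from these steps cover counting error only. As no counts are given, a gene at exactly 0 is called listed at 0, and no fold is given against it.

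Rows of 1 symbol were summed, and 13 rows that the authors' table marks as too deep to test or as failed were left out, a choice made after the table was read. The measure of difference was log2((resistant FPKM + 1)/(wild type FPKM + 1)), which understates differences of low genes, for genes at 1 FPKM or more in at least 1 library. Genes with a log2 ratio of at least 1 in size are called at least 2-fold higher or lower. With 1 library per group no test, p-value or error across libraries was computed. Gene lists of the drug's pathway, cell state and other cell types were fixed before the data were examined, together with the named genes rule, the groups and the alternatives. For each list with at least 3 measured genes, the median log2 ratio was set against the medians of 10000 random lists of the same size matched on expression in 20 bins, and a median beyond the central 95% of these was described as outside. A single list symbol was not matched to the table. Windows of 10 measured genes on each side of a gene were ranked among all such windows, and gene order was shuffled 1000 times for the most extreme medians.

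The named genes are the 12 with the highest and the 12 with the lowest ratio among genes whose higher value is at least 5 FPKM, leaving out predicted and clone names, pseudogenes, small RNAs, mitochondrially encoded and ribosomal protein genes. All measured genes of the gemcitabine lists belong to them too. So do up to 2 members in each direction with a log2 ratio of at least 1 in size from every other list that stood apart or held at least 3 such genes, as well as the reference genes and pancreatic cancer drivers. Small RNAs were recognised by annotated type as well as by name, a detail settled after the ranking was seen. Any other gene is said where it appears to have been named by position or after its values were seen. Some genes that the rule takes are not reported here.

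The other settings tried were pseudocounts of 0.1 and 5, no level filter, a filter of 5 FPKM, rescaling the resistant library to a median log2 ratio of 0 or to the same upper quartile, the row with the highest mean for each symbol, a fold threshold of 4, leaving out predicted genes, pseudogenes and small RNAs, random lists without matching, and windows of 5 or 20 genes on each side. Windows of 1 gene, protein-coding genes only, and subtraction of each chromosome's median were added after the data had been seen. A trend in GC content and length was removed as a cubic surface over the longest transcript of each gene, for 99.9% of measured genes. Copies of Gapdh were sought with BLAST 2.17.0+ among all annotated transcripts. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

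The steps were tested on simulated data: fragments were drawn around the wild type values of 19349 genes, with 200 single genes, 2 lists, a segment and a chromosome altered. The 200 single genes were all at 5 FPKM or more in the wild type library. Of those altered 4-fold or 8-fold, in either direction, 100% passed the 2-fold line. Of those altered exactly 2-fold 11.8% (higher) and 15.2% (lower) did, since the pseudocount pulls ratios toward 0. Genes between 1 and 5 FPKM were not covered, and near 1 FPKM the pseudocount can keep a gene lowered 4-fold or 8-fold from passing the line. Counting noise alone put 0.18% of unaltered genes past 2-fold. A list raised 2-fold and a list lowered 2-fold were at the 100 and 0 percentiles, and 3 of 25 lists with no altered gene lay outside the central 95%. A chromosome lowered by a factor of 0.75 had a median of -0.39, and the highest window fell in the raised segment.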

Results

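KPC2 is a mouse pancreatic cancer line, and the series set untreated KPC2 cells beside a derivative kept for a long time in 260 ng/mL gemcitabine, a deoxycytidine analogue that cells phosphorylate and build into DNA. RNA was sequenced from 1 wild type and 1 gemcitabine-resistant library. The deposited values per gene and library carry no named unit and were read as FPKM. There were no replicates, so every difference below describes these 2 libraries, with no test between the conditions. Only the resistant cells were kept in gemcitabine. For every gene and list below, drug in the medium and a lasting state of the resistant cells therefore cannot be told apart. A gene counted as measured at 1 FPKM or more in at least 1 library, which held for 12193 genes, 10561 of them protein-coding. Low values fell on whole-fragment steps, from which 1 FPKM on a 2 kb transcript, less a fitted 160 bases, rested on about 44.1 fragments in the wild type and 42.7 in the resistant library. Counting error alone then spans 0.72 to 1.34 FPKM in the wild type library and 0.73 to 1.36 FPKM in the resistant one (exact Poisson, 95%).

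Resistant against wild type cells, Rrm1, the large subunit of ribonucleotide reductase and a known target of gemcitabine, stood at 2501 FPKM against 71.5 FPKM, a log2 ratio of 5.11. Other genes with the highest ratios were Rhox5, an X-linked homeobox gene (319.5 against 0.42 FPKM), the chemokine gene Ccl20 (381 against 6.25), the stress-inducible gene Gadd45a (299.9 against 4.88), the calcium sensor gene Stim1 (296 against 5.81) and the small GTPase gene Rhog (884 against 19.5). Arhgdib (46.5 against 0.44), Ccn1 (177 against 4.64), the non-coding RNA gene Lncenc1 (24.7 against 0.08), Atf3 (53.1 against 2.29) and Chac1 (106.7 against 6.10) followed. Clca3b stood at 18.3 FPKM in the resistant library and was listed at 0 in the wild type. At the other end, the X-linked genes Tceal9 (0.20 against 42.9 FPKM) and Bex3 (0.14 against 38.1), the heat shock gene Hspa1b (0.13 against 15.2), Ambp (0.77 against 28.0) and the heparan sulfate sulfatase gene Sulf2 (1.09 against 27.1) were lower in resistant cells. Clic6, Dhrs3, Marcksl1, Podxl, the methionine adenosyltransferase gene Mat2a (8.27 against 70.5 FPKM) and the efflux transporter gene Abcg2 (0.45 against 9.97) were also among the 12 lowest ratios. In all, 963 measured genes were at least 2-fold higher in resistant cells on the log2(FPKM + 1) scale, 1021 were at least 2-fold lower, and 83.7% lay within 2-fold. At a pseudocount of 5 the counts were 428 and 297, and at a pseudocount of 0.1 the lower count was 1553.

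The authors' deposited table, which holds their own test of the 2 libraries, called 56 genes, 37 higher and 19 lower in resistant cells. It listed 22 of these at 0 in the wild type library and 16 at 0 in the resistant one. In the authors' deposited table the calls included Rrm1, Stim1, Rhog, Ccl20, Gadd45a, Ccn1, Clca3b and Gapdh. The authors did not call Rhox5, Arhgdib, Lncenc1, Atf3 and Chac1 of the 12 highest ratios, and of the 12 lowest ratios they called Gapdh alone. Among the other calls of the authors' deposited table were Rhox2h (10.7 FPKM in resistant cells, listed at 0 in wild type), Hoxa10 (2.58 FPKM, listed at 0 in wild type), and Peg3 and Maged2 (4.52 and 6.27 FPKM in wild type, listed at 0 in resistant cells), 4 genes chosen after their values were seen.

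Among genes that move and metabolise gemcitabine, the nucleoside transporter gene Slc29a1 was lower in resistant cells, at 31.5 against 83.0 FPKM (log2 ratio -1.37). Dck, whose product carries out the first phosphorylation of the drug, stood at 8.18 against 15.3 FPKM (log2 ratio -0.83), and the mitochondrial kinase gene Tk2 at 1.99 against 4.01 FPKM. On the log2(FPKM + 1) scale none of the 5 activation genes differed by 2-fold or more, though the FPKM of Tk2 taken as such were 2.02-fold apart, and Cmpk1, Nme1 and Nme2 had log2 ratios of 0.29, 0.06 and 0.48. Of the 10 genes in the fixed list for gemcitabine inactivation, Nt5c2, a nucleotidase gene, was at least 2-fold lower (15.7 against 37.5 FPKM) and the other 9 lay within 2-fold. Among them, cytidine deaminase, Cda, stood at 11.01 against 9.04 FPKM and Nt5e at 44.4 against 22.9 FPKM. Slc29a2 and Slc29a3 were near the level filter, at 1.51 against 1.34 and 1.00 against 2.47 FPKM. The medians of the uptake, activation and inactivation lists (-0.79, 0.06 and -0.14) lay inside the central 95% of random lists.

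The 3 ribonucleotide reductase genes had a median log2 ratio of 1.34, outside the central 95% of random lists (-0.69 to 0.89). With 3 genes this median is the log2 ratio of Rrm2b itself, between Rrm1 at 5.11 and Rrm2 at -0.55. Besides Rrm1, the p53-inducible small subunit gene Rrm2b was higher in resistant cells (8.91 against 2.92 FPKM), while Rrm2, the small subunit of dividing cells, stood at 166 against 244 FPKM. Of 7 measured drug efflux ABC transporter genes, Abcc1 (42.4 against 15.5 FPKM) and Abcc5 (103.7 against 42.8) were at least 2-fold higher, Abcg2 was lower, and Abcb1a, Abcb1b, Abcc3 and Abcc4 lay within 2-fold. The list's median of 0.31 lay inside its random range of -0.52 to 0.57.

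**Figure D1:**
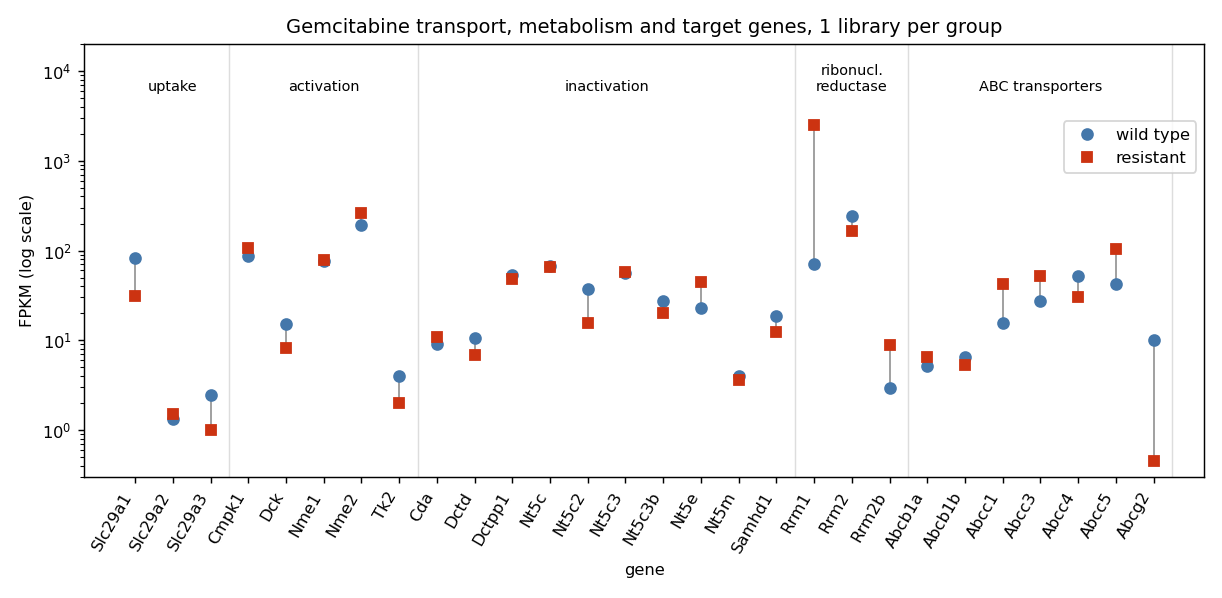
FPKM on a log axis of the measured genes of gemcitabine uptake, activation and inactivation, ribonucleotide reductase and drug efflux ABC transporters in the wild type library (circles) and the resistant library (squares), 1 library each, with a line joining both values of a gene. Rrm1 shows the widest gap upward (71.5 to 2501 FPKM) and Abcg2 the widest gap downward (9.97 to 0.45 FPKM).

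Rhog, Stim1 and Rrm1 are consecutive protein-coding genes on chromosome 7 of GRCm38, at 102239123 to 102256054, 102267806 to 102437319 and 102441695 to 102469771. Their FPKM values in resistant cells were 45.2, 50.9 and 35.0 times those in the wild type. The nearest measured protein-coding genes, named by position, were much closer between the libraries: Pgap2 stood at 15.8 against 9.34 FPKM, Nup98 at 25.0 against 24.0 and Trim68 at 1.37 against 1.25, and the 5 genes on each side had a median log2 ratio of 0.06, with Fam160a2 the highest at 1.37. The planned window of 10 measured genes on each side of Rrm1 had a median log2 ratio of 0.12, the 64.0 percentile of 11767 such windows over the genome. Around Dck on chromosome 5 the window's median was 0.49, the 96.4 percentile, but with 20 genes on each side it was 0.08, the 58.0 percentile. The highest window median, 1.06, lay on chromosome 9 from 65587160 to 67559703, where 12 of 21 genes were at least 2-fold higher, among them Dapk2, Herc1 and Usp3, named after their values were seen. The lowest, -0.999, lay on chromosome 13 from 67121660 to 68582149, where 10 of 21 genes were at least 2-fold lower, all of them zinc finger genes such as Zfp65 and Zfp748, named likewise. With gene order shuffled 1000 times, the most extreme window medians were 0.99 and -1.05, so the lowest window did not pass what shuffling gave.

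**Figure D2:**
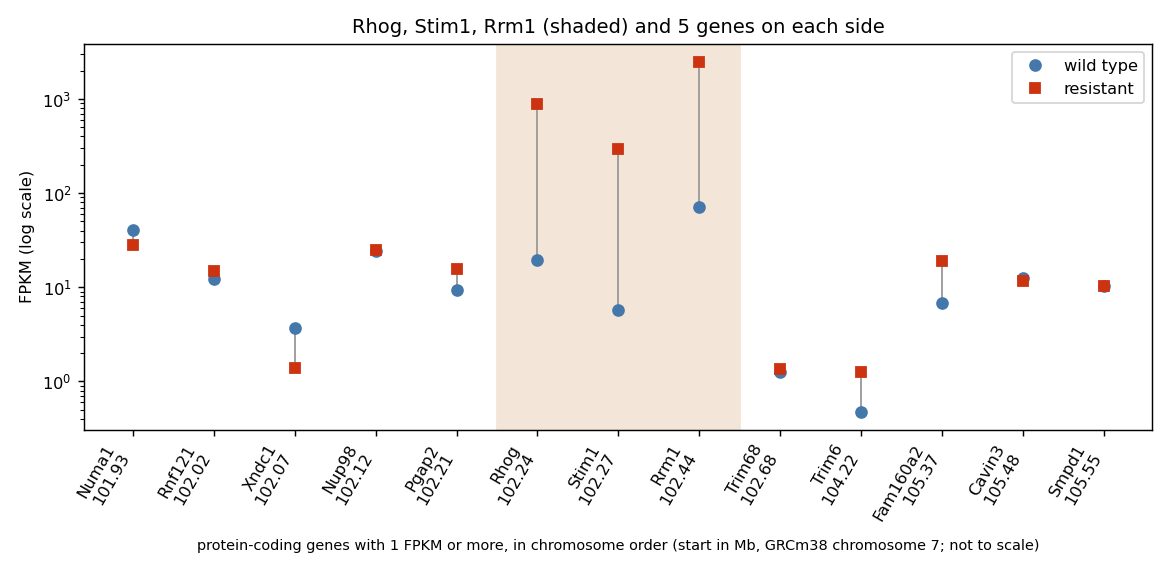
FPKM on a log axis of Rhog, Stim1 and Rrm1 (shaded) and of the 5 nearest measured protein-coding genes on each side, in their order on GRCm38 chromosome 7, in the wild type library (circles) and the resistant library (squares). The 3 shaded genes are 35.0 to 50.9 times higher in the resistant library, while the median log2 ratio of the 10 flanking genes is 0.06.

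Genes of the integrated stress response and the unfolded protein response were higher in resistant cells: all 23 had a log2 ratio above 0, 14 were at least 2-fold higher and 9 lay within 2-fold. The transcription factor gene Atf3 (53.1 against 2.29 FPKM) and Chac1, which encodes a glutathione-degrading enzyme (106.7 against 6.10 FPKM), led the list. Its median of 1.25 lay above the central 95% of random lists (-0.13 to 0.39). Of 24 measured NRF2 and glutathione genes, 6 were at least 2-fold higher and none 2-fold lower, with heme oxygenase, Hmox1 (88.3 against 8.06 FPKM), and Osgin1 (246 against 40.3) in front and a median of 0.46 above the range of -0.08 to 0.39. Lysosome and autophagy genes had a median of 0.46 against -0.24 to 0.38, with 4 of 20 at least 2-fold higher, led by the autophagy receptor gene Sqstm1 (605 against 132 FPKM) and Neu1 (80.4 against 22.8). Of 22 measured p53 targets, 4 were at least 2-fold higher, Plk2 (60.9 against 8.50 FPKM) and the BH3-only gene Pmaip1 (39.7 against 7.17) with the highest ratios, and the median of 0.41 lay above -0.34 to 0.32. Trp53 itself stood at 50.0 against 82.0 FPKM.

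Inflammatory cytokine and NF-kB genes were higher as a group, with 9 of 21 measured genes at least 2-fold higher, none 2-fold lower and a median of 0.89 above the random range of -0.35 to 0.36. Ccl20 and the interleukin-1 receptor antagonist gene Il1rn (193 against 15.1 FPKM) had the highest ratios. Of 13 leukocyte markers, the 2 measured were higher too, Cd68 (5.48 against 1.17 FPKM) and Lyz2 (1.53 against 0.36), both named after their values were seen. Type I interferon response genes were mostly under 1 FPKM. Of the 9 measured, 3 were at least 2-fold higher, among them Ddx58 (4.88 against 1.60 FPKM) and Oas1a, near the filter and named after its values were seen (1.20 against 0.02). The list's median of 0.97 lay above -0.72 to 0.55, and lay inside its range at 96.0 and 96.6 percentiles without the level filter and with a filter of 5 FPKM. TGF-beta targets had a median of 0.51 above -0.38 to 0.44, with 4 of 14 at least 2-fold higher, among them Id3 (22.4 against 3.89 FPKM), and Id2 lower (55.8 against 144.2). That list lay inside its range at a pseudocount of 5 and at a filter of 5 FPKM.

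Markers of the basal-like pancreatic cancer subtype were measured for 5 of 20 genes, all above 0 and 3 at least 2-fold higher: Krt14 (47.0 against 8.51 FPKM), the EGFR ligand gene Areg (103.0 against 20.5) and Sprr1a (1789 against 411), the last named after its values were seen. Their median was 2.12 against a random range of -0.53 to 0.68. The classical subtype list was mixed, with 4 of 17 measured genes at least 2-fold higher and 1 lower: the trefoil factor gene Tff3 stood at 262 against 34.3 FPKM and Ceacam1 at 6.57 against 0.29, and cathepsin E, Ctse, at 15.4 against 92.4. Its median of 0.14 lay inside its range of -0.26 to 0.41. Medians of the epithelial (0.23) and mesenchymal (0.11) identity lists lay inside theirs too, with Krt7 (32.6 against 7.56 FPKM) and Fn1 (18.6 against 2.93) higher and Crb3 (9.26 against 24.1), Ocln (2.61 against 7.13) and S100a4 (366 against 898) lower. The receptor gene Egfr stood at 8.12 against 0.93 FPKM and Erbb2 at 4.82 against 13.1.

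Lower in resistant cells were replication-dependent histone genes, 7 of 19 at least 2-fold lower and 1 higher, with linker histones H1f1 (82.0 against 328 FPKM) and H1f5 (132.6 against 406) lowest and H2bc4 higher (180.9 against 85.7). Their median of -0.39 lay below the random range of -0.11 to 0.43. DNA replication genes had a median of -0.25 below -0.21 to 0.32, with 4 of 26 at least 2-fold lower, among them the cyclin gene Ccne2 (1.5 against 17.4 FPKM) and the flap endonuclease gene Fen1 (10.5 against 43.1). Without matching on expression, the 5.25 percentile of that list lay inside the central 95%. Of 20 homologous recombination and Fanconi anaemia genes, 4 were at least 2-fold lower, among them Fancm (2.18 against 5.85 FPKM) and Brca2, and the list's median of -0.39 lay just inside its range. Mitosis genes had a median of -0.02, inside their range.

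Of 12 driver and tumour suppressor genes of pancreatic cancer, Cdkn2a and Cdkn2b were listed at 0 in both libraries, and the 10 measured had a median of -0.58 below the random range of -0.36 to 0.48. At least 2-fold lower were 2 of them, Brca2 (1.74 against 4.65 FPKM) among these, and Smad4 stood at 27.9 FPKM in both libraries. Of 15 common reference genes, Gapdh alone differed by 2-fold or more: 15.2 FPKM in resistant against 297 FPKM in wild type cells. Gapdh has 176 entries in the table with near-identical copies of its sequence (at least 90% identity over at least 500 bases), so its level is uncertain. With those copies added, and each entry weighted by the length of its longest annotated transcript, the total was 9.29 times lower in resistant cells. The expressed transcripts can be shorter, so the size of that factor depends on the lengths taken. Unweighted, the copies without Gapdh summed to 55.3 FPKM in resistant against 37.8 FPKM in wild type cells. They include the protein-coding gene Peli2 (0.10 against 2.66 FPKM), named after its values were seen, whose own fall enters the total. The other 14 reference genes lay within 2-fold, among them Tbp (10.0 against 18.9 FPKM) and B2m (160.7 against 83.03 FPKM).

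Most markers of other cell types of the pancreas were below 1 FPKM in both libraries, all 12 fibroblast and all 10 islet markers among them. Besides the leukocyte markers Cd68 and Lyz2, those at 1 FPKM or more were Cela1 of 13 acinar markers (1.48 against 4.38 FPKM) and Egfl7 of 9 endothelial markers (10.2 against 7.48 FPKM), named after their values were seen. The 4 Y-linked genes were listed at 0 in both libraries, and Xist stood at 5.75 against 27.7 FPKM.

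Several other lists had medians inside their random ranges while some of their members differed by 2-fold or more. Of 20 glycolysis genes, 5 were at least 2-fold higher and 2 lower (median 0.35). The phosphofructokinase gene Pfkp stood at 38.1 against 5.17 FPKM. The 2 lower ones were Gapdh, whose level is uncertain as said above, and the lactate transporter gene Slc16a3 (0.28 against 2.94 FPKM). Sterol synthesis genes had 5 of 22 at least 2-fold higher, among them Hsd17b7 (16.7 against 5.09 FPKM), and a median of 0.33. In the hypoxia list, Vegfa (50.04 against 13.5 FPKM) and Ddit4 (44.9 against 13.5) were higher and Egln1 (7.05 against 16.6) lower (median 0.16). Of 23 MAPK output genes 6 were at least 2-fold higher, Areg and Spry1 (17.4 against 6.17 FPKM) most (median 0.11). YAP and TEAD targets included Ccn1, Gadd45b (19.3 against 2.58 FPKM) and Foxf2 (5.94 against 20.02), with a median of 0.05. Among 11 extracellular matrix genes, 3 were at least 2-fold higher, Thbs1 most (14.4 against 0.72 FPKM, list median -0.03). Stem-like markers had 5 of 13 at least 2-fold lower, among them Aldh1a3 (0.43 against 5.97 FPKM), and Aldh1a7 higher (10.7 against 1.44). In the xenobiotic metabolism list, Gstt1 (12.9 against 2.91 FPKM) and Tiparp (18.4 against 4.70) were higher (median 0.30). Of 16 pro-apoptotic genes, Bbc3 (6.23 against 1.43 FPKM) and Pmaip1 were at least 2-fold higher and Bad (10.09 against 35.3) lower. Replication stress checkpoint genes had 3 of 17 at least 2-fold lower, Cdc25a (4.42 against 10.9 FPKM) and Topbp1 (17.4 against 38.5) most, and a median of -0.30.

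Over the fixed lists, 41 of 47 had at least 3 measured genes. Of these 41 medians, 12 lay outside the central 95% of their random lists, 9 above and 3 below. About 2.05 would by chance if genes varied independently, but the ranges are too narrow where members of a list vary together. In the simulated data 3 of 25 lists with no altered gene lay outside, so the number by chance may be higher than 2.05. The lists share genes, so the 12 are not independent counts.

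**Figure D3:**
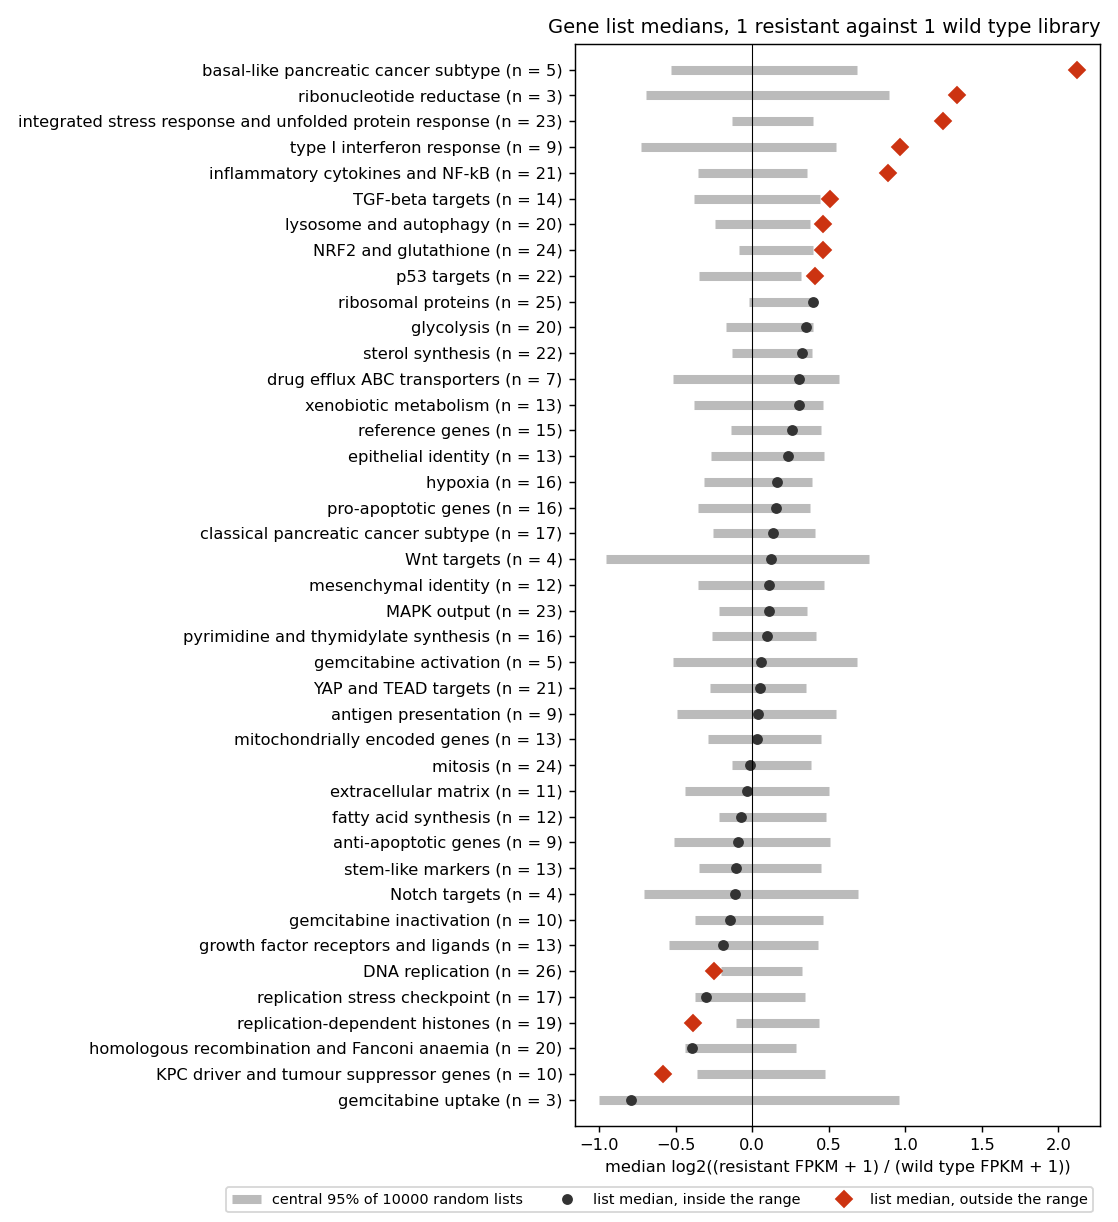
Median log2 ratio of FPKM + 1, resistant over wild type, of each list with at least 3 measured genes (n is the number measured), with grey bars for the central 95% of medians of 10000 random lists matched on expression. Diamonds mark the 12 medians outside their bar, from -0.58 for driver and tumour suppressor genes to 2.12 for basal-like markers.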

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

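Of the 13 rows left out of the comparison because the authors' table marks them as failed or too deep to test, 1 stood at 1 FPKM or more and above the wild type: Phf3, which encodes a PHD finger protein, at 49.3 FPKM in resistant against 36.9 FPKM in wild type cells. Of the same 13, Gm26917, Rn7s2 and Rn7s1 stood at 11084.5, 710.2 and 315.2 FPKM in wild type and were listed at 0 in resistant cells. These rows carry the mark of too deep to test, and others so marked, such as AY036118 and Gm42418, were listed at 0 in both libraries. A 0 in such a row can stand for a value that was not estimated, so no difference is read from them. No explanation was tested for these values.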

How the results depend on the processing

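Windows of 1 gene, protein-coding genes only, chromosome centring and every chromosome alternative were chosen after the data were seen, and the other alternatives were planned. The 2 rescalings shifted log2 ratios by -0.06 and -0.05 and ended no list's call. The counts of genes at least 2-fold higher and lower (963 and 1021) moved past 1.5 times to 428 and 297 at a pseudocount of 5, to 220 and 128 at a fold threshold of 4 and, for the lower genes, to 1553 at a pseudocount of 0.1, where the construction itself shifts low genes across the line. Of the 12 lists that stood apart, 9 did so under each of the alternatives run. TGF-beta targets had medians of 0.28 at a pseudocount of 5 and 0.50 with a filter of 5 FPKM, type I interferon genes 0.0885 without the level filter and 0.97 with a filter of 5 FPKM, and DNA replication genes -0.25 against unmatched random lists, each inside its random range there, and the cause was not tested. Lists inside their random ranges could also pass out of them: homologous recombination and Fanconi anaemia genes (1.64 percentile) and ribosomal proteins (99.01) against unmatched random lists, ribosomal proteins among protein-coding genes (97.68), and gemcitabine uptake (2.2), replication stress checkpoint (0.55), sterol synthesis (99.1) and stem-like markers (2.355) with chromosome medians subtracted, where the cause was not tested. Without the level filter 45 lists could be read and 12 lay outside their ranges, 11 of which also did so with the filter of 1 FPKM. The remaining list had too few measured genes to be read with that filter. Around Dck, the window median of 0.49 was 0.53 with 5 genes on each side, 0.08 with 20 and -0.02 with 1. The stress response list kept a median of 1.12 to 1.25 over 10 alternatives. With 1 gene on each side of Rrm1, the window median was 3.97, or 2.76 among protein-coding genes, because Stim1 then makes up one side. In the window at 3.97 the other side is the non-coding entry Gm45399 (log2 ratio 2.49), which lies inside Rrm1 and can take its fragments. Of 127 named genes, which were run under the pseudocount, level filter, rescaling and symbol alternatives and no others, 93 moved by less than 1.5-fold under each of these, the rest moved by more with a pseudocount alone, and no gene past 2-fold turned its sign. The chromosome 19 median ranged from -0.48 to -0.18 and that of chromosome 1 from 0.05 to 0.45 over 8 alternatives, nearest 0 without the level filter. Counting error is widest near 1 FPKM, and the lack of replicates leaves biological spread unknown.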

Other observations

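The family scan, the runs of neighbouring genes, the tests of overlapping loci, of a wide segment around Rrm1 and of drug in the medium, the subtraction of chromosome medians and all tests on chromosomes 1 and 19 were chosen after the values they build on had been seen. Among 165 families of protein-coding genes grouped by symbol stem, with at least 8 measured genes each, 10 had medians below the central 95% of random lists and 8 above. If genes varied independently, 8.25 in all would by chance, but the random ranges are too narrow where members of a family vary together. Zinc finger genes named Zfp were lower as a group, 64 of 273 at least 2-fold lower and 7 higher (median -0.64, random range -0.21 to 0.02), and so were Zbtb genes (8 of 33 at least 2-fold lower, median -0.61) and splicing factor genes named Srsf (4 of 10, median -0.79). Aldehyde dehydrogenase genes were higher, 7 of 16 by at least 2-fold and 1 lower (median 0.72), as were aldo-keto reductase genes named Akr (5 of 11, median 0.84), Serpinb genes (5 of 9, median 1.20) and the phosphatase family Dusp (5 of 17, median 0.60). With chromosome medians subtracted, the Dusp median was 0.38, and those of Zfp, Zbtb, Srsf, Aldh, Akr and Serpinb were -0.60, -0.64, -0.90, 0.70, 0.70 and 1.20.

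Rrm1, Stim1 and Rhog form the single run of 3 neighbouring protein-coding genes at least 8-fold higher, and 0 of 1000 shuffles of gene order gave such a run. Against fragments counted for several overlapping gene models at once, 0 pairs of the 3 loci in the authors' table overlap, and against a gain wide enough to hold 10 expressed genes on each side, that window stood at the 64.0 percentile. A gain of the short segment that holds the 3 genes, 230.6 kb, is a candidate explanation: its 2 non-coding entries summed to 6.98 FPKM in resistant against 0.48 FPKM in wild type cells, a ratio of 14.5 that met the bound of 4 set for a gain before these values were seen. Both entries lie inside Stim1 or Rrm1 and can take fragments of those genes, a weakness of the test recognised only after its values were seen, so the result was left open. A gain and higher transcription of the 3 genes cannot be told apart here, because DNA was not analysed.

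The stress response list, with a median of 1.25 and 23 of 23 genes above 0, was set against 3 explanations. Across genes the log2 ratio had almost no trend in GC content or length (Spearman -0.001 and -0.09, 0.82% of the variance), so removing it was a mild correction, and the list's median after it was 1.21, too far from 0 for a trend of that size to be the whole cause. With each chromosome's median subtracted the list's median was 1.12, at the 100 percentile of random lists. The highest chromosome median was 0.36, on chromosome 1, so this subtraction could not have brought the list into its random range. The values show only that whole-chromosome shifts of that size are too small to be the whole cause. Whether it goes with gemcitabine in the medium at harvest or with a lasting state of the resistant cells cannot be told apart, since 0 libraries of resistant cells grown without gemcitabine are among those analysed.

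On chromosome 19, 89 of 438 measured genes were at least 2-fold lower and 15 higher (median -0.43, random range -0.05 to 0.09), Nt5c2, Fen1 and Bad among the lower ones, and on chromosome 1, 94 of 712 were higher and 30 lower (median 0.36, random range -0.04 to 0.06). These medians depend on the level filter, without which they were -0.18 and 0.05, and the random ranges, which 9 of 20 chromosomes lay below and 9 above, treat genes as independent and so are too narrow where neighbours vary together. Removing the same small GC and length trend left chromosome 19 at -0.44, and all 4 of its parts of near-equal gene number lay below their ranges, which argues against that trend and against a few clusters as the whole cause. The highest median among these 4 parts and its lower and higher expressed genes was -0.36, consistent with a lower copy number of the whole of chromosome 19 in resistant cells. That stays a hypothesis found and tested on the same 2 libraries, with no DNA analysed here, and the bound it met was written when the chromosome's median was known.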
